A study of Homo sapiens with 6 samples.

How the data were processed

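Gene expression was measured by RNA sequencing of total RNA from UMUC3 cells in 6 libraries, 3 infected with the TIM-1 vector and 3 with the empty vector. Groups were taken from the treatment given in the labels, and replicate numbers from the sample titles. The authors deposited 1 table of raw gene counts, whole numbers of reads per Ensembl gene with no normalization, with 1 column per library and 60605 genes. Reads were aligned to hg38 with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, and DESeq2 1.16.1 was used, per the submitters' processing notes. The annotation release, the strand setting and the rule for multi-mapping reads are not given in the sources used here. Reads from overlapping genes, antisense genes and near-identical copies may therefore have been split between them or left out, which can change the counts of such genes.

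Gene symbols were found for 60463 of the 60605 identifiers, and 58337 were present in GENCODE 29, which is built on GRCh38, the same assembly as hg38, and gave positions, biotypes, exon lengths and GC content. Of the entries of the gene lists, 575 were matched by symbol, 21 by an older annotation name and 7 by a synonym, and 0 stayed unmatched. All rows of the table named a gene. Total counts ran from 14312387 to 18605914 per library, and at least 99.8% of the counts of each library lay in tested genes. The 10 most abundant genes took between 6.81% and 7.76% of the counts, and genes encoded by mitochondrial DNA between 4.20% and 5.08%. Intervals and detection limits cover counting error only. A count of 0 was taken to allow up to 3 counts, and the interval of the pooled HAVCR1 ratio is an exact 95% interval conditional on the total count.

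Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM normalization factors) in R 4.3.3. Genes were kept with the filterByExpr function with a minimum count of 10, which left 14479. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The design compared the groups with no other term. Log2 fold changes are TIM-1 minus empty vector, standard errors were derived from the F statistic, and CPM values use the TMM-scaled library sizes. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the residual degrees of freedom, 4 in this design and 2 in the blocked fit described below, so it is a weak test here. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes.

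Because both groups carry replicate numbers 1 to 3, a fit with the number as a block was planned as an alternative. The pairing comes from the data, since the labels give the numbers without saying what they mark. The deviations of same-numbered libraries from their group means, over genes, correlated at 0.53 for replicate 1, 0.23 for replicate 2 and 0.26 for replicate 3. Between different numbers the correlations ran from -0.40 to 0.26. The highest was 0.26, between TIM-1 replicate 3 and empty-vector replicate 2, so replicates 2 and 3 are told apart weakly, while replicate 1 stands apart from both. All 3 pairs lay above the limit of 0.1 set for taking the numbers as pairs, and the blocked results are therefore given beside the unpaired ones. TIM-1 replicate 2 with empty-vector replicate 3 (0.19) and TIM-1 replicate 3 with empty-vector replicate 2 (0.26) lay above it too. Deviations cancel out within a group, so a replicate 1 that stands apart in both groups can bring this about. The limit therefore backs the pairing of replicate 1 only. The blocked fit has 2 residual degrees of freedom. After the data were seen it was also treated as a result of its own, with its own alternatives.

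Within-group pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 4.16 and 27.5, so no library was counted as a copy of another.

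Named genes followed a fixed rule. HAVCR1 and IFIT2 came first, as the study's title names them. Next came up to 10 genes per direction with the largest log2 fold change among protein-coding genes past the threshold, with a mean of at least 1 CPM and no overlap between the groups. In each list up to 3 called members with the smallest p were named, or up to 2 of the highest mean CPM where none was called. After the data were seen, the same rule was applied to the blocked fit. Genes named outside the rule are marked as such.

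The unpaired and the blocked tests were tested on simulated data with 14479 genes drawn from the means and library sizes of these libraries. Of genes changed by 0.5, 1 and 2 on the log2 scale, the unpaired test recovered 17.9%, 76.1% and 93.9%, with 11 false calls among 14259 unchanged genes. The blocked test recovered 73.1%, 88.1% and 100%, with 8 false calls. Each test met data drawn from its own design, the blocked one with its fitted block effects and dispersions. The simulation therefore does not test whether the numbers mark pairs. A list shifted by 0.3 in the simulation was found by camera in both fits and an unshifted list was not. Simulated genes were drawn independently of one another, so this does not test the preset correlation. A rate of false list calls was not measured.

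Alternatives were other size factors (those of DESeq2 1.42.0, or library size alone), no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, removal of HAVCR1, a minimum log2 fold change of 1, the block, and leaving out each library. Added after the data were seen were leaving out same-numbered pairs, a block that only sets replicate 1 against the others, and lowess corrections of each library for GC content or exon length. The replicate 1 difference was tested in edgeR with the group and the replicate number as terms.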

Results

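RNA sequencing was carried out on UMUC3 cells, an established human bladder cancer cell line, infected with lentivirus. The virus carried either TIM-1 in a pLVX vector that also encodes the green fluorescent protein ZsGreen, or the same vector without TIM-1. TIM-1 is a cell surface receptor for phosphatidylserine, encoded by HAVCR1. Each group held 3 libraries, numbered 1 to 3 in both groups. Total gene counts were 14312387, 16139248 and 18605914 for TIM-1 replicates 1, 2 and 3, and 15651864, 16242133 and 17162935 for empty-vector replicates 1, 2 and 3. Between 21441 and 22220 genes had at least 1 count in a library. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The comparison of the 2 groups addressed which transcripts differ when TIM-1 is expressed, in a study whose title links TIM-1 to proliferation and to the gene IFIT2.

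HAVCR1 was abundant in every TIM-1 library and nearly absent from the empty-vector libraries. The gene (ENSG00000113249) lies on chromosome 5 from 157029413 to 157059119 on the minus strand of GRCh38. Its counts were 7069, 9824 and 11479 in TIM-1 replicates 1, 2 and 3, and 4, 0 and 0 in the empty-vector replicates. In counts-per-million (CPM) units, the level was 572 ± 73.0 CPM (SD, n = 3) with TIM-1 and 0.0835 ± 0.145 CPM (SD, n = 3) with the empty vector. Per read sequenced, HAVCR1 was 7093-fold higher over the pooled libraries (exact 95% interval for the counts, 2770 to 26034, counting error only). All 4 empty-vector counts came from replicate 1, so without that library the fold has only a lower bound. The counts of 0 in empty-vector replicates 2 and 3 allow up to 0.185 and 0.175 CPM. The counts do not separate vector transcripts from those of the chromosomal gene.

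With TIM-1, HAVCR1 and MAGEC2, a cancer-testis antigen gene of the MAGE family, rose in the test that treated the libraries as unpaired. MAGEC2 stood at 52.3 ± 3.73 CPM with TIM-1 and 26.4 ± 1.17 CPM with the empty vector (SD, n = 3 each). With same-numbered libraries taken as pairs, 466 genes rose and 259 fell. Genes that rose included 9 of hypoxia and glycolysis such as NDRG1, 10 of the extracellular matrix such as COL5A1, 5 of MHC class I presentation and 9 interferon-stimulated genes such as LGALS3BP. Genes that fell included 13 of cholesterol synthesis such as HMGCS1, 9 of the ATF4 and amino acid response such as SLC7A11, 7 NF-kB targets and 5 replication-dependent histone genes. None of these list genes passed without the pairing. The data back the pairing of replicate 1 only. A block that only set replicate 1 against the others gave 348 genes higher and 162 lower, all among the paired calls. All of the called hypoxia, cholesterol, ATF4 and NF-kB genes also differed between replicate 1 and replicates 2 and 3, in the same direction as with TIM-1.

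In the unpaired edgeR quasi-likelihood test of 14479 genes, 2 genes were higher and 0 lower at the adjusted threshold, and 795 genes had an unadjusted p under 0.05. For MAGEC2 the log2 fold change was 0.99 (SE 0.10, edgeR adjusted p = 0.0185), and for HAVCR1 it was 12.64 (SE 0.36, edgeR adjusted p = 3.45e-06). DESeq2 without pairing, run without the low-count filter, called 24 genes higher and 1 lower, and all 25 were among the genes of the paired test. Leaving out empty-vector replicate 1 gave 8 higher and 1 lower. Leaving out any of the other 5 libraries left HAVCR1 alone, with MAGEC2 at edgeR adjusted p = 0.0595 without TIM-1 replicate 1, 0.0971 without TIM-1 replicate 2, 0.225 without TIM-1 replicate 3, 0.186 without empty-vector replicate 2 and 0.260 without empty-vector replicate 3. The log2 fold change of MAGEC2 stayed between 0.94 and 1.04 when each of the 6 libraries was left out.

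With the replicate number as a block, the edgeR test called 725 genes, of which 662 were protein coding. At least a 2-fold difference was reached by 72 of the higher and 6 of the lower genes, and the median absolute log2 fold change of the called genes was 0.39. The direction was the same in all 3 pairs for 714 of the 725, against 39.2% of all tested genes and 25% by chance. The 3 values of one group lay outside those of the other for 357 of the 725 (49.2%), against 11.7% of all tested genes and 10% by chance. The test selected the 725 for steady changes within pairs, which raises both shares, so neither is further evidence. The biological coefficient of variation was 14.2% without the block and 6.67% with it. Without the replicate 1 pair the paired test called 440 genes higher and 398 lower, without the replicate 2 pair 152 and 57, and without the replicate 3 pair 339 and 134. DESeq2 with the block, run on 28529 genes without the low-count filter, called 131 higher and 78 lower. A correction for the GC content of genes, with the block, gave 685 higher and 627 lower, a share of 52.2% higher against 64.3%.

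**Figure D1:**
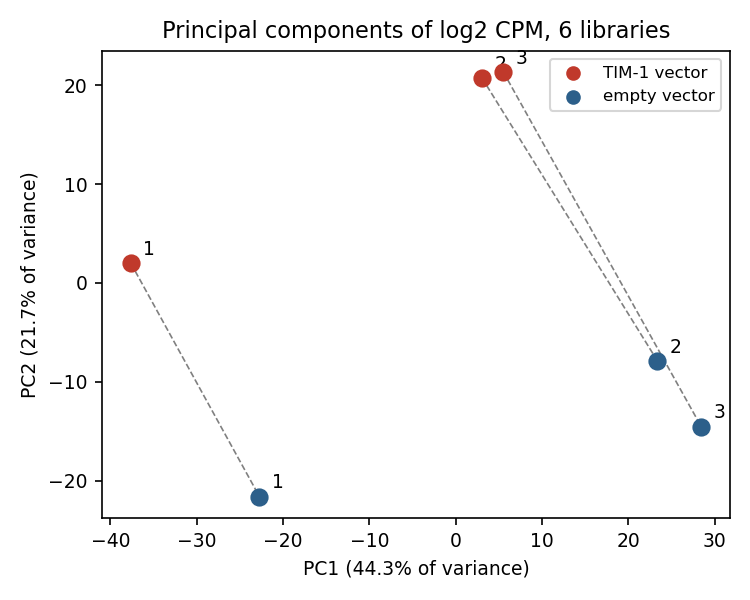
First principal component (x axis, 44.3% of variance) against the second (y axis, 21.7%) of log2 CPM for the 6 libraries; dashed lines join libraries of the same number. Both replicate 1 libraries lie at negative values of the first component and the other 4 at positive values, while within each pair the TIM-1 library lies above the empty-vector library on the second. Within each pair the TIM-1 library also lies lower on the first component, toward the side of replicate 1.

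Replicate 1 stood apart from replicates 2 and 3 in both groups. With the group as a term, 1912 genes were higher and 1912 lower in replicate 1 (edgeR quasi-likelihood test), against 6 genes that differed between replicates 2 and 3. Among those genes, chosen after their values were seen, the chemokine genes CXCL1 and CXCL8 were lower in replicate 1 by log2 differences of -3.02 and -2.91. The hypoxia-responsive genes CA12 and PFKFB4 were higher by 1.41 and 1.64. Across the 14479 tested genes, the TIM-1 change and the replicate 1 difference had a Pearson correlation of 0.24 and a Spearman correlation of 0.29, with genes that are not independent replicates.

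IFIT2, which encodes an interferon-induced RNA-binding protein, was higher with TIM-1 in each of the 3 pairs and passed the test when the libraries were paired. The gene (ENSG00000119922) lies on chromosome 10 from 89283694 to 89309276 on the plus strand. Its counts were 81, 70 and 76 in TIM-1 replicates 1, 2 and 3, and 59, 29 and 22 in the empty-vector replicates. This gave 4.67 ± 0.80 CPM against 2.27 ± 1.25 CPM (SD, n = 3 each), with no overlap between the groups. The unpaired log2 fold change was 1.04 (SE 0.35, edgeR adjusted p = 0.775), and the paired one was 1.10 (SE 0.24, edgeR adjusted p = 0.00272). The unpaired log2 fold change ran from 0.76 without empty-vector replicate 3 to 1.57 without empty-vector replicate 1 (edgeR adjusted p = 0.0888). The paired adjusted p was 0.0572 without the replicate 2 pair and 0.116 by DESeq2 with the block. IFIT2 was also higher in replicate 1 than in replicates 2 and 3, by 0.77 on the log2 scale (edgeR adjusted p = 0.0171). The study's title names IFIT2, so it may have been chosen on these samples, and its direction here is not independent evidence. Its annotated span overlaps that of LIPA, and the strand setting of the counting is not given in the sources used here.

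**Figure D2:**
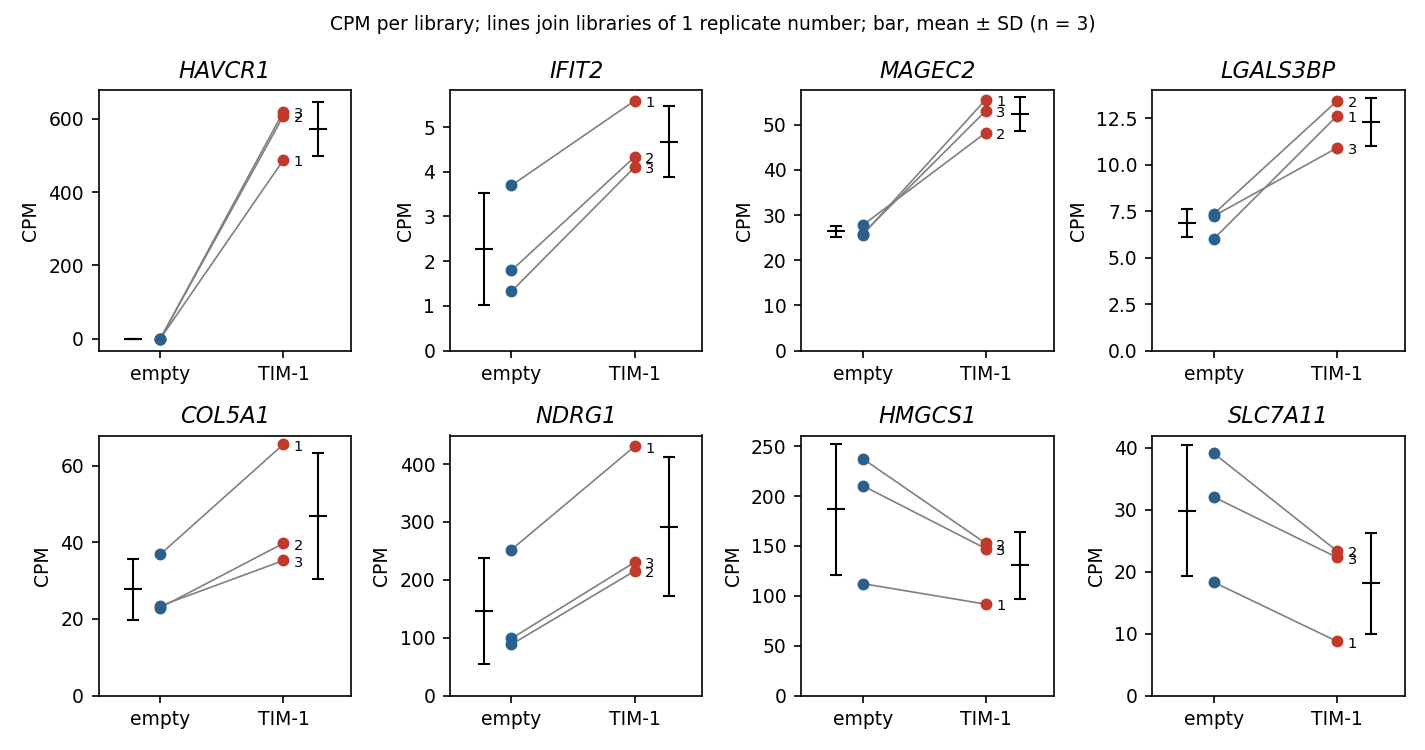
CPM of 8 genes in each library (y axes, linear from 0), with the empty vector in blue and TIM-1 in red; lines join libraries of the same number and bars give the mean ± SD of 3 libraries. MAGEC2, IFIT2 and LGALS3BP separate the groups without overlap, while NDRG1, COL5A1, HMGCS1 and SLC7A11 differ within each pair but overlap between groups.

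Beyond HAVCR1, the largest increases in the paired test were those of SFRP1, ALPK1 and CDK18. SFRP1, a secreted antagonist of Wnt signalling, stood at 4.05 ± 0.306 CPM with TIM-1 and 0.966 ± 0.321 CPM with the empty vector (SD, n = 3 each; log2 fold change 2.07, edgeR adjusted p = 2.86e-06). ALPK1, an innate immune kinase, rose by 1.77 and CDK18, a cyclin-dependent kinase, by 1.69 on the log2 scale. Both had low counts, for ALPK1 49, 54 and 35 with TIM-1 and 15, 9 and 16 with the empty vector. Those of CDK18 were 55, 29 and 38, and 22, 8 and 9. CDK18 was also higher in replicate 1 than in replicates 2 and 3, by 1.13 (edgeR adjusted p = 0.0143). Its empty-vector mean of 0.805 CPM was 0.519 CPM without empty-vector replicate 1. WDR72, HECW2, SPON2, BTBD8, KLF9 and KLF14 rose by 1.36 to 1.47. The largest decreases were those of DHRS2, a short-chain dehydrogenase, from 2.63 ± 0.365 to 0.481 ± 0.614 CPM (SD, n = 3 each; log2 fold change -2.60, edgeR adjusted p = 0.0150), and of the histone gene H4C14, with a log2 fold change of -1.94. DHRS2 had 17, 0 and 5 counts in TIM-1 replicates 1, 2 and 3 and 37, 49 and 42 in the empty-vector replicates. Without TIM-1 replicate 1 its TIM-1 mean was 0.135 CPM, and without the replicate 1 pair its log2 fold change was -4.22. GATA3, a transcription factor of luminal urothelium, fell by 1.25 on the log2 scale. PROZ, SLC25A45, ZNF268, FAAP24 and LRFN5, together with the histone genes H2BC11 and H2AC6, had log2 fold changes between -0.53 and -0.96. Of these 20 genes with HAVCR1, 7 stayed called without each pair in turn, namely HAVCR1, SFRP1, CDK18, KLF9, DHRS2, H2BC11 and H2AC6. Fits without a pair have fewer residual degrees of freedom than the full blocked fit, and their p can fall as data are removed. The edgeR adjusted p of H2AC6 went from 4.22e-08 to 8.14e-10 without the replicate 3 pair, so staying called is weak evidence of stability. Without the replicate 1 pair 3 of the 20 were lost, without the replicate 2 pair 11, and without the replicate 3 pair 10. DESeq2 with the block called 6 of the 20, gave CDK18 an adjusted p of 0.0693 and gave 7, among them DHRS2, no adjusted p.

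Of 27 gene lists fixed before the data were examined, as were the unpaired design and the rule for naming genes, 23 had at least 5 tested members. Camera with a preset correlation called 11 lists without the block (6 up and 5 down) and 13 with it (6 up and 7 down), the 11 among them. With an estimated correlation 0 lists were called in either fit, with adjusted p from 0.177 to 0.945 over the 11 lists and from 0.151 to 0.688 over the 13. Unadjusted p under 0.05 was then reached by 3 lists without the block and 7 with it. With the block the estimated correlation was below the preset 0.01 for the TIM family (-0.070), NRF2 (-0.053) and NF-kB (-0.036) lists. So it was for the interferon (-0.018), MHC class I (-0.010) and histone (0.0078) lists. For the other called lists it ran from 0.027 (extracellular matrix) to 0.57 (ribosomal proteins), with 0.15 for cholesterol synthesis, 0.21 for G1/S and 0.34 for heat shock. Without the block it was higher for most called lists, reaching 0.73 for hypoxia and 0.81 for both cholesterol synthesis and ribosomal proteins. For lists with such correlations, camera p at the preset 0.01 can be far too small. Where it was below 0.01 with the block, correlation between genes does not account for the lost call, and the few residual degrees of freedom limit this test. Fry called 1 list in each fit, that of the TIM family with HAVCR1. Without the block HAVCR1 was the only list member to pass the threshold over all genes, and the member counts and log2 fold changes given for each list come from the paired test. Of 62 called genes named by the rule, 33 stayed called without each pair in turn, and 8, 23 and 19 were lost without the pairs of replicates 1, 2 and 3. The edgeR adjusted p of BIRC3 fell from 0.000275 to 1.05e-14 without the replicate 3 pair, so here too staying called is weak evidence of stability. DESeq2 with the block called 36 of the 62. With a block that only set replicate 1 against the others, 8 of the 62 were lost. B2M, PPARG, CCND1, HECW2, SPON2 and KLF14 were lost without each of the 3 pairs.

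Of 35 tested interferon-stimulated genes 9 rose with TIM-1 and 0 fell, and adjusted over the list alone 9 rose and 1 fell. LGALS3BP, a secreted galectin-binding protein, rose by 0.84 on the log2 scale, SAMD9 by 1.34 and the antiviral membrane protein gene IFITM3 by 0.37, which was lost without the replicate 2 pair (edgeR adjusted p = 0.0602). The IFIT2 relatives IFIT1 and IFIT3, named after their values were seen, rose by 0.60 and 0.70. The list had a median log2 fold change of 0.17 (camera adjusted p = 3.75e-06 with the block and 2.76e-06 without it; adjusted p = 0.151 and 0.177 with an estimated correlation). IFIT2 is a member of this list, whose choice followed the study's title, so the direction is not fully independent of these samples. Of 11 nucleic acid sensing genes 0 passed, also when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.506), and MAVS stood at 0.10 and TRAF3 at -0.05.

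Of 17 tested genes of MHC class I antigen presentation 5 rose with TIM-1 and 0 fell, and adjusted over the list alone 7 rose and 1 fell. The immunoproteasome subunit gene PSMB8 rose by 0.90, HLA-E by 0.30 and B2M, the MHC class I light chain, by 0.24 on the log2 scale. With a pair left out each of these calls was lost, PSMB8 without replicate 3 (edgeR adjusted p = 0.0980), HLA-E without replicate 2 (0.148) and B2M without replicates 1, 2 and 3 (0.0512, 0.0641 and 0.145). By DESeq2 with the block their adjusted p was 0.138, 0.0420 and 0.0607. The median was 0.21 (camera adjusted p = 0.000992 with the block and 0.00336 without it; adjusted p = 0.163 and 0.573 with an estimated correlation). Without the block the call was lost without TIM-1 replicate 3 (camera adjusted p = 0.0886) and without empty-vector replicate 1 (0.580). In replicate 1 against replicates 2 and 3, the MHC class I list had a median log2 difference of -0.35 and the interferon list one of -0.15. HLA genes are near-identical to one another, and reads can be split between them.

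Of 22 tested hypoxia and glycolysis genes 9 rose with TIM-1 and 0 fell, and adjusted over the list alone 15 rose and 0 fell. NDRG1, a stress-responsive gene, went from 146 ± 91.7 to 292 ± 120 CPM (SD, n = 3 each), with a log2 fold change of 1.08, the glucose transporter gene SLC2A1 rose by 0.64 and the enolase gene ENO2 by 0.47. Without empty-vector replicate 1 the empty-vector mean of NDRG1 was 93.6 CPM. The median was 0.32 (camera adjusted p = 2.64e-16 with the block and 0.000289 without it; adjusted p = 0.151 and 0.643 with an estimated correlation). GAPDH and ENO1, the most abundant members, had log2 fold changes of 0.18 and 0.03. Without the block the call was lost without TIM-1 replicate 1 (camera adjusted p = 0.322). Replicate 1 differed from replicates 2 and 3 by a median of 0.57 over the same list. Outside the lists and named after their values were seen, the hypoxia-responsive genes CA12, STC1 and DEPP1 rose by 0.99, 1.20 and 1.66, and IGFBP3, which encodes an insulin-like growth factor binding protein, by 0.90. CA12, STC1 and DEPP1 were also higher in replicate 1, by 1.41, 1.53 and 2.02. The hypoxia-responsive genes PFKFB4 and ANGPTL4, higher in replicate 1 by 1.64 and 1.35, had TIM-1 log2 fold changes of 0.32 (edgeR adjusted p = 0.0606) and 0.26 (edgeR adjusted p = 0.0407).

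Of 22 tested cholesterol synthesis genes 0 rose with TIM-1 and 13 fell, and adjusted over the list alone 15 fell. HMGCS1, which encodes the synthase upstream of HMG-CoA reductase, fell by 0.49 on the log2 scale, MVD by 0.45 and MSMO1 by 0.43. The median was -0.26 (camera adjusted p = 6.22e-15 with the block and 2.53e-06 without it; adjusted p = 0.158 and 0.573 with an estimated correlation). Of 20 tested genes of the ATF4 and amino acid response 1 rose and 9 fell, or 1 and 11 adjusted over the list alone. The cystine transporter gene SLC7A11 fell by 0.74 and the serine synthesis gene PSAT1 by 0.54, while DDIT4, an inhibitor of mTORC1 that hypoxia also induces, rose by 0.39. The median was -0.20 (camera adjusted p = 5.74e-08 with the block and 0.000929 without it; adjusted p = 0.155 and 0.570 with an estimated correlation). Without the block the ATF4 call was lost without TIM-1 replicate 1 (camera adjusted p = 0.0664). Of 16 NRF2 and antioxidant genes 0 rose and 3 fell, namely SLC7A11, the haem oxygenase gene HMOX1 (-0.41) and PGD (-0.22), and adjusted over the list alone 4 fell. PGD was lost without replicate 2 (edgeR adjusted p = 0.378) and replicate 3 (0.0776). That list was called with the block (median -0.04, camera adjusted p = 0.00503) and not without it (0.345), and had adjusted p = 0.196 with an estimated correlation. Without the block the NRF2 list was called without empty-vector replicate 1 (camera adjusted p = 0.00611), without TIM-1 replicate 3 (0.0441) and without both replicate 1 libraries (0.0176), and it reached 0.958 without empty-vector replicate 3. The replicate 1 differences of these 3 lists had medians of -0.42, -0.46 and -0.39.

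Of 20 tested extracellular matrix genes 10 rose with TIM-1 and 0 fell, and adjusted over the list alone 12 rose. COL5A1, a fibrillar collagen gene, went from 27.7 ± 7.89 to 46.8 ± 16.4 CPM, with a log2 fold change of 0.74, the laminin gene LAMB3 from 18.9 ± 1.24 to 33.3 ± 1.93 CPM (SD, n = 3 each), with 0.81, and COL1A1 rose by 0.90. The median was 0.24 (camera adjusted p = 5.41e-11 with the block and 4.91e-07 without it; adjusted p = 0.151 and 0.285 with an estimated correlation), and the replicate 1 difference had a median of 0.28. Of 21 epithelial-mesenchymal genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone. The matrix metalloproteinase genes MMP2 and MMP14 rose by 0.83 and 0.31 and TGFBI by 0.33, and as a list these genes were not called (median 0.06, camera adjusted p = 0.108). Without the replicate 2 pair MMP14 (edgeR adjusted p = 0.0911) and TGFBI (0.0602) were lost. Of 10 urothelial genes PPARG rose by 0.62 and GATA3 and the keratin gene KRT18 (-0.24) fell, also when adjusted over the list alone. KRT18 was lost without replicate 2 (edgeR adjusted p = 0.0632) and replicate 3 (0.147), as was GATA3 (0.319 and 0.382). That list had a median of 0.06, a mean of -0.05 and a test direction of down (camera adjusted p = 0.665).

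Of 21 tested NF-kB target genes, among them cytokines and chemokines, 0 rose with TIM-1 and 7 fell, and adjusted over the list alone 9 fell. NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, fell by 0.58 on the log2 scale, the chemokine gene CXCL2 by 0.47 and BIRC3, an apoptosis inhibitor gene, by 0.48 (adjusted p = 0.113 by DESeq2 with the block). The median was -0.17 (camera adjusted p = 2.43e-06; adjusted p = 0.151 with an estimated correlation). Without the block the list was not called (camera adjusted p = 0.288), and its median replicate 1 difference was -1.57. Left-out libraries moved that unblocked p widely. It was 6.40e-06 without empty-vector replicate 1, 0.0301 without TIM-1 replicate 2, 0.00792 without TIM-1 replicate 3, 7.97e-06 without both replicate 1 libraries and 0.883 without empty-vector replicate 2. Of 25 tested immediate early genes 3 rose and 3 fell, or 3 and 4 adjusted over the list alone. The phosphatase gene DUSP4 rose by 0.78, whereas FOSB fell by 0.62 and MYC by 0.35, and the list was not called (median -0.01, mean 0.02, test direction down, camera adjusted p = 0.665). Its replicate 1 difference had a median of -0.69.

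**Figure D3:**
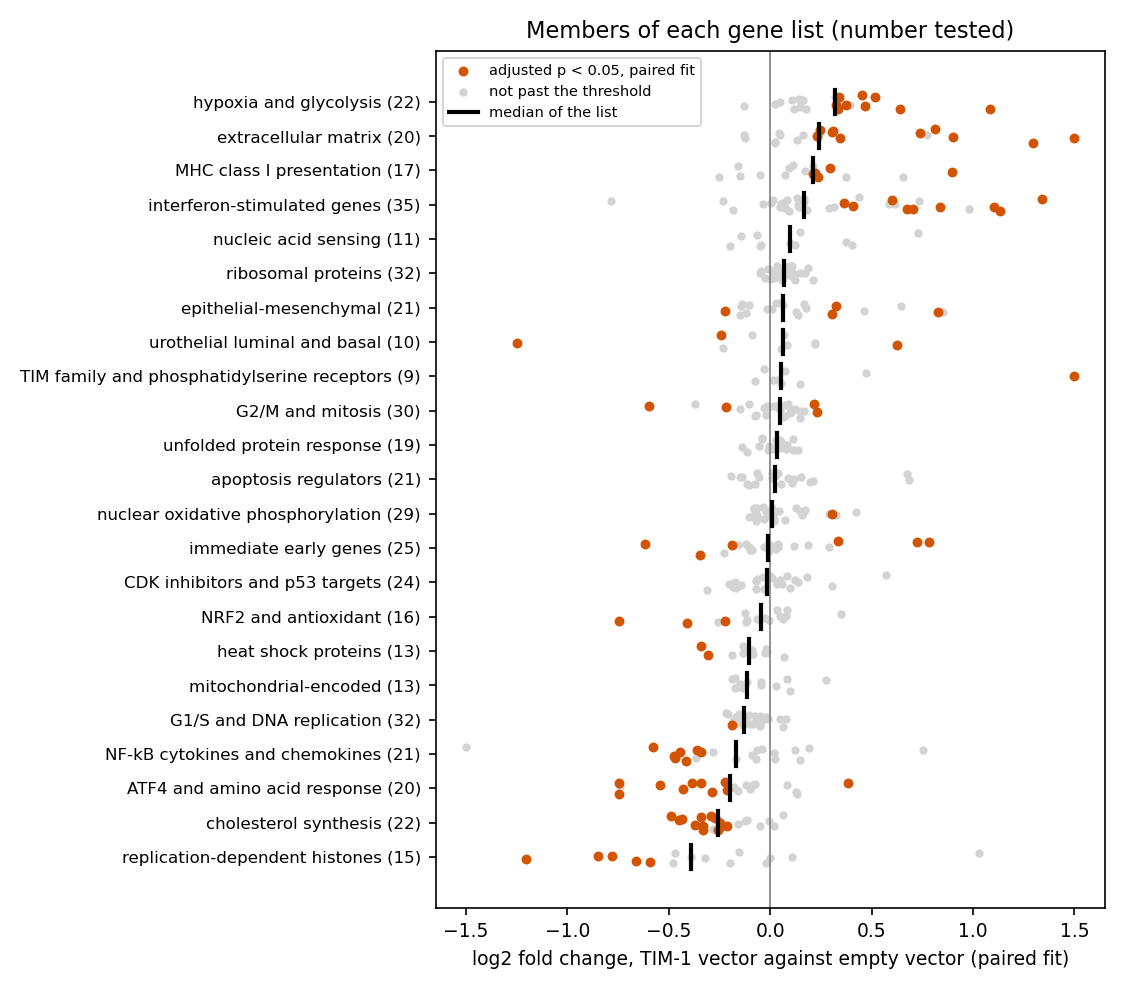
Paired log2 fold change (x axis) of each tested member of the 23 lists, with the number tested in brackets; orange points passed the adjusted threshold over all genes, grey points did not, and black bars give list medians. The 3 members beyond 1.5 in either direction are drawn at the edge of the axis. Medians run from -0.39 for replication-dependent histones to 0.32 for hypoxia and glycolysis.

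Among the proliferation lists, 1 of 32 tested G1/S and DNA replication genes passed the test. The cyclin D1 gene CCND1 fell by 0.19 on the log2 scale, and adjusted over the list alone 0 passed. The median was -0.13 (camera adjusted p = 4.77e-06 with the block and 4.27e-05 without it; adjusted p = 0.357 and 0.570 with an estimated correlation), and the replicate 1 difference had a median of -0.12. The most abundant members, MCM7 and RRM2, had log2 fold changes of -0.12 and -0.17. CCND1 was not called without any of the 3 pairs in turn (edgeR adjusted p = 0.0522, 0.406 and 0.171 without replicates 1, 2 and 3). Of 30 G2/M and mitosis genes 2 rose and 2 fell, the same numbers as adjusted over the list alone. The kinesin gene KIF20A rose by 0.23 and the cyclin B2 gene CCNB2 by 0.22, whereas the kinetochore motor gene CENPE fell by 0.60. KIF20A was lost without replicate 2 (edgeR adjusted p = 0.321) and replicate 3 (0.0935), and CCNB2 likewise (0.320 and 0.170). CENPE stayed called without each pair, at -0.40 without replicate 3, and its TIM-1 mean of 61.8 CPM was 36.2 CPM without TIM-1 replicate 1. Its edgeR adjusted p fell from 0.0189 to 1.12e-06, 1.22e-05 and 0.00011 without the pairs of replicates 1, 2 and 3. Fits without a pair have few residual degrees of freedom, so these p are weak evidence of stability. DESeq2 with the block called none of these 3 genes (adjusted p = 0.0705, 0.188 and 0.222). The G2/M list was not called (median 0.05, camera adjusted p = 0.530), and its replicate 1 difference had a median of 0.53. The replication-dependent histone list was fixed beforehand as a marker of RNA quality, not of proliferation, and which of these its change reflects was not tested. Of its 15 tested genes 0 rose and 5 fell, or 1 and 6 adjusted over the list alone. H2AC6 went from 39.6 ± 8.04 to 23.1 ± 4.93 CPM (SD, n = 3 each), with a log2 fold change of -0.78, while H1-2 fell by 0.66 and H4C8 by 1.21. The median was -0.39 (camera adjusted p = 5.00e-07 with the block and 0.000929 without it; adjusted p = 0.151 and 0.570 with an estimated correlation). Its replicate 1 difference had a median of -0.52, and histone genes have near-identical copies that can share reads.

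Of 24 CDK inhibitor and p53 target genes 0 passed, with 1 higher and 1 lower when adjusted over the list alone (median -0.02, mean 0.00, camera adjusted p = 0.623). GADD45A stood at -0.17 and CDKN2C at 0.09. Of 21 apoptosis regulators 0 passed, also when adjusted over the list alone (median 0.02, camera adjusted p = 0.987), and MCL1 stood at -0.07 and CYCS at -0.19. The unfolded protein response list had 0 of 19 members called, also when adjusted over the list alone, with HSPA5 at 0.05 (median 0.03, camera adjusted p = 0.530; replicate 1 median -0.55). Of 29 nuclear oxidative phosphorylation genes NDUFA1 rose by 0.31 (0.17 without the replicate 3 pair, edgeR adjusted p = 0.392), also when adjusted over the list alone (median 0.01, camera adjusted p = 0.704). Of 13 genes encoded by mitochondrial DNA 0 passed, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.0591; replicate 1 median -0.13). With the block that list was called without replicate 1 (camera adjusted p = 0.0307) and without replicate 2 (0.00722), and not without replicate 3 (0.658). Without the block it was not called (0.252), but was without empty-vector replicate 1 (0.0300) and without empty-vector replicate 2 (0.0285); adjusted p = 0.945 with an estimated correlation and all 6 libraries.

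Of 13 heat shock protein genes HSPA8 fell by 0.31 and HSPA1B by 0.34, and adjusted over the list alone 3 fell. Both genes were lost without the replicate 1 pair (edgeR adjusted p = 0.0751 and 0.0639). The heat shock list was called down (median -0.10, camera adjusted p = 0.000522 with the block and 0.00434 without it; adjusted p = 0.400 and 0.404 with an estimated correlation), and with the block not without replicate 1 (0.133), nor without the block when both replicate 1 libraries were left out (0.0808). Its replicate 1 difference had a median of -0.05. HSPA1B and its near-identical copy HSPA1A can share reads. Of 32 ribosomal protein genes 0 passed, also when adjusted over the list alone, and RPL4 and RPL8 stood at 0.08 and 0.00. The ribosomal list was called up (median 0.07, camera adjusted p = 0.00503 with the block and 0.0137 without it; adjusted p = 0.688 and 0.945 with an estimated correlation). With the block that call was lost without replicate 1 (0.147) and without replicate 3 (0.308), and the replicate 1 difference had a median of -0.14. Of 9 tested TIM family and phosphatidylserine receptor genes HAVCR1 alone rose over all genes, and 2 rose adjusted over the list alone. That list was called up (median 0.05, camera adjusted p = 0.000210 with the block and 0.00717 without it; adjusted p = 0.158 and 0.285 with an estimated correlation), and not after HAVCR1 and IFIT2 were left out (camera adjusted p = 0.287 and 0.405).

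Most markers of other cell types were too low to test. Of 15 T and B lymphocyte markers 0 were abundant enough to test, and the most abundant had 52 reads over the 6 libraries. Of 13 myeloid markers ITGAM alone was tested, with a log2 fold change of -0.35 (edgeR adjusted p = 0.558 with the block). Of 13 fibroblast markers 3 were tested and COL1A1 rose, which is also in the matrix list, while TAGLN stood at 0.09. Of 12 endothelial markers 2 were tested. ENG, which encodes the TGF-beta co-receptor endoglin, stood at 38.5 ± 2.91 CPM with TIM-1 and 44.3 ± 5.42 CPM with the empty vector (SD, n = 3 each), with a log2 fold change of -0.20. ESAM stood at -0.38, and neither passed the test.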

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

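The corrections for GC content and exon length, the fits without a pair, the fit without both replicate 1 libraries and the block that sets replicate 1 against the others were chosen after the data were seen. Without the block, 2 genes were higher and 0 lower. Those counts were unchanged with DESeq2 size factors, library size alone, the CPM filter, limma-voom and the GC correction. They became 60 and 12 with no low-count filter, 24 and 1 by DESeq2, 175 and 82 without both replicate 1 libraries, and 466 and 259 with the replicate block. DESeq2 was run on 28529 genes without that filter, so test and filter changed together. The higher count became 4 with the length correction, 1 at a log2 fold change of at least 1 and 1 without HAVCR1, which follows from its removal. Leaving out each library gave 1 to 8 higher and 0 to 1 lower. The 2 unblocked calls stayed among the blocked ones, and 238 of the 257 calls without both replicate 1 libraries were among the 725.

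With the replicate block, 466 were higher and 259 lower, against 2 and 0 without it. DESeq2, again on 28529 genes without the low-count filter, gave 131 and 78, all 209 among the 725. Leaving out each pair gave 152 to 440 higher and 57 to 398 lower, with fewer samples in each fit. With the block of replicate 1 against the others the counts became 348 and 162, all 510 among the 725. The lower count became 627 with the GC correction, which kept 722 of the 725. At a log2 fold change of at least 1 the counts were 72 and 6. The other alternatives stayed within 1.5 times. Scaling by library size alone moved the median of all genes by 0.01 (log2). The block turned the direction of 0 of the 62 named genes, most of which were chosen from the blocked test. Without the block, leaving out each library gave log2 fold changes of -0.75 to 0.035 for BIRC3 and -0.037 to 0.54 for KIF20A, which turned without TIM-1 replicate 1. For 7 named-gene values DESeq2 gave no adjusted p. Apart from the removals, the cause was not tested.

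Of the gene lists, 11 were called without the block and 13 with it, which added the NF-kB and NRF2 lists and changed no other call. With an estimated correlation 0 were called in either fit, and by fry 1 without and 1 with the block. Without the block, leaving out each library gave camera adjusted p from 5.76e-05 to 0.182 for the G2/M list, 0.000708 to 0.556 for the unfolded protein response, 0.000103 to 0.990 for ribosomal proteins and 0.000708 to 0.726 for immediate early genes. The direction turned for G2/M without TIM-1 replicate 1 (0.000228), for ribosomal proteins without TIM-1 replicate 3 (0.959) and empty-vector replicate 1 (0.990), and for the unfolded protein response (0.0389) and immediate early genes (0.0418) without empty-vector replicate 1. Without TIM-1 replicate 3 the epithelial-mesenchymal and G2/M lists were called (0.0464 each), and without empty-vector replicate 3 the immediate early list was (0.0296). Without both replicate 1 libraries the ribosomal call was lost (0.111). IFIT2 had 22 to 81 counts and NDRG1 1431 to 6240, so counting error is larger for IFIT2. The SE was larger for NDRG1 without the block (0.53 against 0.35) and smaller with it (0.08 against 0.24), so depth was not what limited NDRG1 without the block.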

Other observations

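In this part, the test of a shared culture or handling day and the tests of a shift of culture state by gene list, with the tallies of list members and of genes not called with TIM-1, were chosen only after the result was seen. Beyond the TIM-1 comparison, the genes that set replicate 1 apart form groups. Of 21 NF-kB target genes 18 were lower and 1 higher in replicate 1 than in replicates 2 and 3 (edgeR adjusted over all genes). The list had a median log2 difference of -1.57 (camera adjusted p = 1.95e-28; adjusted p = 0.0662 with an estimated correlation). BIRC3 was lower by -1.80 and CXCL2 by -2.33. Of 30 G2/M and mitosis genes 27 were higher and 0 lower, with a median of 0.53 (camera adjusted p = 2.48e-31; adjusted p = 0.0662 with an estimated correlation). CENPE was higher by 1.39 and ASPM, a spindle pole gene, by 1.27. Of 19 unfolded protein response genes 15 were lower and 1 higher, and DDIT3, a stress-induced transcription factor gene, was lower by -2.82 (camera adjusted p = 3.18e-18 for the list; adjusted p = 0.0662 with an estimated correlation). Of 22 hypoxia and glycolysis genes 19 were higher and 0 lower (median 0.57, camera adjusted p = 9.34e-22; adjusted p = 0.0865 with an estimated correlation).

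The 2 genes called without pairing were compared with the other splits of the 6 libraries. The real split was the 1 of 10 splits with as many, and the highest of the others gave 0. With the block, the real split gave 725 genes and was the 1 of the 4 splits that part all 3 pairs to give as many, the others giving 0. Both sets of splits are too few for a share under 0.05.

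Replicate 1 differed from replicates 2 and 3 at 3824 genes. After thinning every library to the smallest total, 95.2% of these stayed called, which argues against lower depth as the whole cause. Of those with a known GC content and exon length, 99.9% stayed called after a GC correction and 85.3% after a length correction, which argues against those trends as the whole cause. A shared culture or handling day for same-numbered libraries is consistent with the correlation of 0.53 between the deviations of the replicate 1 libraries. It cannot be told apart from another shared source, since the labels do not say what a number marks, and no biological explanation was tested.

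The TIM-1 change lay partly along the replicate 1 difference. Of the 725 genes called with the block, 357 were also called in replicate 1 in the same direction, 44 in the opposite direction and 324 not at all. Of the 13754 genes not called with TIM-1, 2388 were called in replicate 1 in the same direction and 1035 in the opposite one. Both comparisons use the same 6 libraries. After a GC correction with the block 722 of the 725 stayed called and after a length correction 686. The GC correction raised the calls to 1312, so staying called after it is weak evidence. Across genes, the TIM-1 change had Spearman correlations of -0.005 with GC content and -0.008 with exon length. These correlations and the length result argue against steady trends with GC content or length as the whole cause. A hypothesis is that part of the TIM-1 change may be a shift of culture state, such as oxygen, density or nutrient supply, between the dishes of a pair. Of the 13 lists called with the block, 9 had replicate 1 medians of the same sign as with TIM-1, and the interferon, MHC class I, ribosomal and TIM family lists had the opposite sign. By camera 3 of these 4 were called in the opposite direction, which by itself would argue against such a shift alone, and with an estimated correlation 0 were. The lowest adjusted p of any list along the replicate 1 difference was then 0.0662, so no list could meet that requirement and it decides nothing. The rule that both calls are needed was set with these signs known, and the test replaced one on fewer of the lists. The ribosomal list was lower in replicate 1 (median -0.14, camera adjusted p = 1.47e-05; adjusted p = 0.445 with an estimated correlation) and higher with TIM-1 (median 0.07, adjusted p = 0.688 with an estimated correlation). Of the genes called with TIM-1, 13 of 13 in the cholesterol list, 10 of 10 in the ATF4 list, 9 of 9 in the hypoxia list, 7 of 7 in the NF-kB list, 3 of 3 in the NRF2 list, 4 of 5 in the histone list and 5 of 10 in the extracellular matrix list were called in replicate 1 in the same direction, and 0 in the opposite one. These values do not tell such a shift apart from an effect of TIM-1 on the same genes. Against such a shift alone, the opposite calls made up 6.07% of the 725 (exact 95% interval 4.44% to 8.06%), but this interval, which treats genes as independent, holds the limit of 5% set beforehand. Over all tested genes, with 26.4% called in replicate 1 and no relation between the directions, 13.2% would be opposite. That figure is no baseline for the 725, which were called in replicate 1 more often than tested genes at large. Among genes called in replicate 1, the opposite share was 10.97% for those also called with TIM-1. For those not called with TIM-1 it was 30.24%.

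The interferon and MHC class I lists had medians of 0.17 and 0.21 with TIM-1, opposite in sign to those in replicate 1. The MHC class I list had a median replicate 1 difference of -0.35 (camera adjusted p = 1.2e-05; adjusted p = 0.111 with an estimated correlation). Of its 5 genes called with TIM-1, B2M and PDIA3 were called in replicate 1 in the opposite direction, HLA-E in the same one and 2 not at all. The interferon list had one of -0.15 (camera adjusted p = 0.0487; adjusted p = 0.276 with an estimated correlation). Of its 9 called genes, PARP9 and IFITM3 were called in the opposite direction, IFIT2, IFI44 and SAMD9 in the same one and 4 not at all. A hypothesis is that part of these lists may respond to TIM-1 apart from whatever sets replicate 1 apart. With an estimated correlation the lowest adjusted p of any list along the replicate 1 difference was 0.0662, so losing both calls that way decides nothing. With called members going both ways, a shift of culture state and this hypothesis are not told apart for these lists.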
